A study of Arabidopsis thaliana with 4 samples.

How the data were processed

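RNA was measured in whole Arabidopsis seedlings, 6 d old, in 2 wild-type libraries and 2 libraries of a ClpD-overexpressing line. Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads, and libraries were made with a NEBNext Ultra RNA kit and sequenced on an Illumina HiSeq instrument. Use of strand in the counting is not given in the sources used here. Reads of a gene and of an overlapping antisense gene therefore cannot be told apart. Per the submitters' processing notes, fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1, RSEM and DESeq2 were used on the build TAIR10, and the notes give these with no role or order.

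The authors deposited 1 table of the whole series. Its estimated counts per gene, per the file headers, are whole numbers that are not normalized, and they were taken to be expected counts because RSEM is named in the notes. Rounding changed none of them. The authors' FPKM values in the same table served only to check the columns, and 7, 7, 11 and 11 genes per library had an FPKM above 0 at a count of 0. With means under 0.001 set to 0.001, the deposited log2 fold change differed by at most 4.28e-09 from the log2 ratio of the authors' mean FPKM values. The p-value and its adjusted value in the deposited table come from a test whose tool the file headers do not state. The table lists 0 organelle-encoded genes. All 31346 loci were found in the RefSeq annotation of assembly TAIR10.1, which was used only for gene kinds and names, and no coordinates are given because the authors' build differs in name. Chromosomes are those in the locus codes.

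Groups were taken from the genotype labels. The replicates of each group were compared before use. The chi-square of counts per degree of freedom was 18.6 between the WT libraries over 19448 genes and 10.2 between the ClpD-OE libraries over 19843 genes with at least 10 counts, so that they differed by more than sampling noise. The SD of the log2 difference across genes was 0.44 between the WT libraries and 0.36 between the ClpD-OE libraries.

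Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr by group and the quasi-likelihood test (estimateDisp, glmQLFit and glmQLFTest at their defaults), with genotype as the only term. TMM factors were 0.907 and 0.943 for WT and 1.07 and 1.09 for ClpD-OE, and the common biological coefficient of variation was 0.140. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. Normalized CPM were computed from the counts with the TMM-scaled library sizes. For a gene with 0 counts in a group, the fold is a bound against a floor of 3 counts over that group. PCR reads without molecular identifiers are not independent molecules, so floors and intervals cover counting error only.

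In all, 29 gene lists with 606 entries were fixed before the data were examined, and the 27 with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over lists. For the agreement of 2 comparisons that share the WT libraries, ClpD-OE libraries were drawn 100 times at the WT mean, and at the level of each WT library, and set against the real WT libraries. Named genes followed a rule fixed at the same time. The rule takes CLPD, then the 6 largest rises and the 6 largest falls among called genes with a mean CPM of at least 5 and no overlap between groups. From each list it takes the called members with the smallest p, up to 4 for the heat lists, 3 for other called lists and 2 for the remaining lists. It also takes HSFA2, HSP101, HSP70-4, HSP90.1, LHCB1.3, RBCS1A, TOC159 and CDC48A whatever their test gave. Clock genes beyond FKF1, PRR9 and COL2, the photosynthesis genes that did not pass, PYK10, CASP1, ADF8 and NRT2.1 were named after their values were seen. ACC2 and LON1 were also named outside the rule, after the results were seen. The sulfur limitation genes beyond LSU1 and ATSDI1 were chosen once the largest changes were known.

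The test was tried on simulated counts for the 18940 tested genes of this comparison, with 200 genes changed. It recovered 12.9% of 70 genes changed 1.5-fold, 75.4% of 65 changed 2-fold and 95.4% of 65 changed 4-fold, and 6 of its 126 calls were of unchanged genes. In a simulation where the 26S proteasome list alone was shifted 1.5-fold, camera with the preset correlation called it and 0 other lists, while its adjusted p was 0.0613 with an estimated correlation and 0.0771 with fry. With 2 libraries per group, those tests thus missed a shift of that size in that draw. Genes were drawn independently, so the simulation cannot show how often the preset correlation calls lists whose genes vary together.

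The alternatives tried were DESeq2 size factors or library totals in place of TMM, no filter or a minimum of 1 CPM in 2 libraries, DESeq2 1.42.0, the legacy quasi-likelihood fit, the replicate number as a block, organelle-encoded genes left out, each library left out in turn, stricter thresholds, and for lists an estimated correlation and fry. DESeq2 with each library left out and the newer quasi-likelihood fit were added after the data were seen. Figures were drawn with matplotlib 3.10.9.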

Results

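Poly(A)-selected RNA from whole Arabidopsis thaliana seedlings, 6 d old, was sequenced in 4 libraries. Of these, 2 came from wild type (WT) and 2 from a line that constitutively overexpresses CLPD (ClpD-OE), a nuclear gene whose product is a chaperone of the chloroplast Clp protease system. By their titles, both ClpD-OE libraries appear to be of the same line, so overexpression cannot be told apart from other traits of that line. Total counts were 20800842 and 21896988 in WT replicates 1 and 2, and 23294451 and 22764333 in ClpD-OE replicates 1 and 2. The deposited table lists 31346 genes, of which 8151 had no count in any library and 18940 were tested. The labels give the genotype and a replicate number, and nothing states that the replicates were separate cultures, so that p-values measure the spread between these samples, which may be technical. The comparison of ClpD-OE with WT addresses how transcript levels differ in seedlings that overexpress the gene of a chloroplast protein, a question the series frames around a response resembling heat shock. Accumulation of the precursor protein was not measured in these data.

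In ClpD-OE, transcripts of the photosynthetic apparatus and of chlorophyll synthesis were lower, with 54 of 57 tested photosynthesis genes called lower and 0 higher. Genes of mitochondrial chaperones, chloroplast protein import and the 26S proteasome were higher as groups. With an estimated correlation none of these 5 list calls held, at an adjusted p = 0.503 for photosynthesis, chlorophyll synthesis and mitochondrial chaperones and an adjusted p = 0.730 for protein import and the proteasome. UPOX, which encodes a mitochondrial protein responsive to oxidative stress, was 10.9-fold higher. Its list of 24 tested oxidative and organelle stress genes had 3 called higher and 2 lower, and was not called (camera adjusted p = 0.445). Of the 25 cytosolic chaperone and co-chaperone genes, 0 were called by edgeR or DESeq2, with 3 at an unadjusted p under 0.05. The WT libraries differed in that list by a median log2 value of -0.63 (replicate 2 minus replicate 1). The sign of its median change depended on which WT library was left out, so the absence of calls does not show the absence of a response. The count of genes called different was 1552, with 812 higher and 740 lower in ClpD-OE, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05.

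CLPD (AT5G51070, chromosome 5), the overexpressed gene, had 149 ± 2.80 normalized CPM in WT and 1770 ± 143 in ClpD-OE (mean ± SD, n = 2 each). Its counts were 2849 and 3037 in the WT libraries and 41739 and 46316 in the ClpD-OE libraries. The difference was 11.9-fold (log2 fold change 3.57, SE 0.0971, edgeR adjusted p = 0.00283), and reads of the transgene and of the endogenous gene cannot be told apart in gene counts. Without ClpD-OE replicate 1 or 2 its log2 fold change was 3.65 or 3.48 and the edgeR adjusted p 0.0674 or 0.0842, while DESeq2 still called it (adjusted p = 1.50e-49 and 9.21e-45). Of 14 other genes of the chloroplast Clp protease, 13 were not called (list adjusted p = 0.729). CLPS1 (AT1G68660), which encodes a substrate adaptor of the protease, was 1.57-fold lower (log2 fold change -0.65, SE 0.114, edgeR adjusted p = 0.0375), and was not called without WT replicate 1 (adjusted p = 0.0857).

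**Figure D1:**
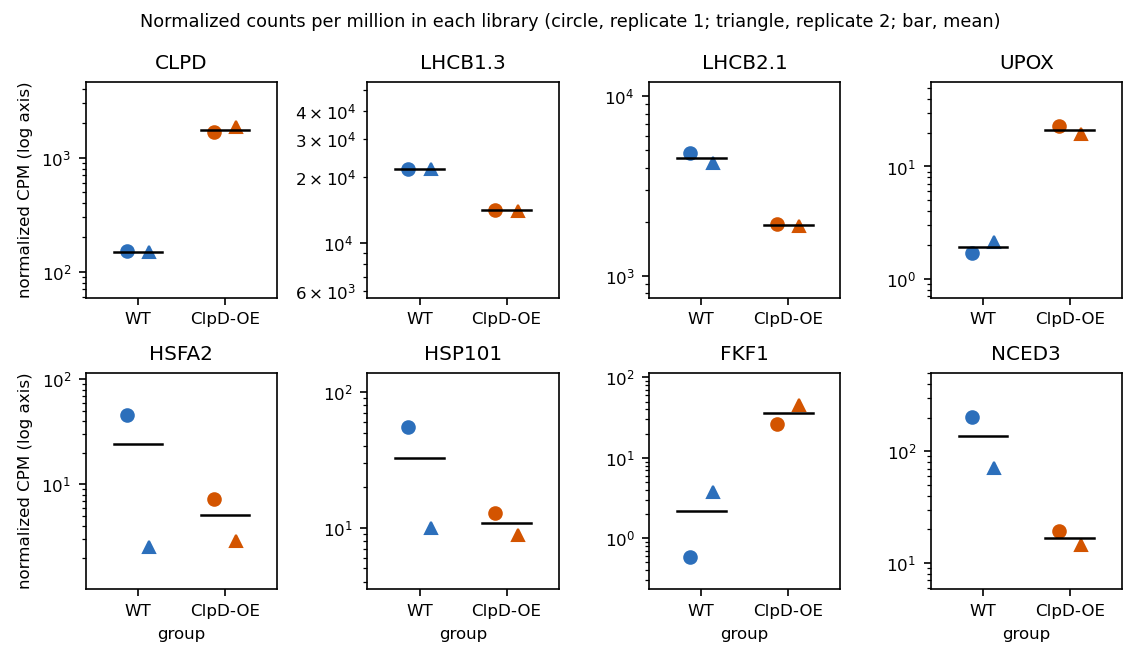
Normalized CPM (log axis) of 8 genes in each library, with WT in blue and ClpD-OE in orange, a circle for replicate 1, a triangle for replicate 2 and a bar for the mean of 2 libraries. CLPD lies near 149 in WT and 1770 in ClpD-OE, while HSFA2 and HSP101 lie at 46.1 and 55.1 in WT replicate 1 and at 2.52 and 9.93 in WT replicate 2.

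Among called genes with a mean of at least 5 normalized CPM and no overlap between the groups, the largest rises were those of COR27 (AT5G42900), a cold-regulated gene tied to the circadian clock, and AT2G04050, annotated as a MATE efflux family gene. COR27 was 38.4-fold higher (log2 fold change 5.26, SE 0.517) and AT2G04050 37.9-fold higher (5.24, SE 0.286). AT4G33980 (28.9-fold, not called by DESeq2 at an adjusted p of 0.187), GRP9 (18.2-fold), AT2G18193 (log2 fold change 4.14) and the blue-light receptor gene FKF1 (16.1-fold) followed. The largest fall was that of AT5G43800, a pseudogene with 272 and 262 counts in the WT libraries and 0 in both ClpD-OE libraries. With a floor of 3 counts over the ClpD-OE group, this makes it at least 224-fold lower, a bound that covers counting error only. NAP (13.1-fold lower), a NAC factor of leaf senescence, and ATSDI1 (9.59-fold lower), a gene induced by sulfur deficiency, came next. NCED3, which encodes a key enzyme of abscisic acid synthesis, went from 135 ± 92.5 to 16.9 ± 3.23 CPM (SD, n = 2), LSU1, a gene of the response to low sulfur, was 7.38-fold lower, and the NAC factor gene RD26 7.07-fold lower. The edgeR adjusted p for these 12 genes lay between 0.0188 and 0.0385. Several of them also differed between the WT libraries, with FKF1 at 11 and 78 counts, COR27 at 2 and 10, AT4G33980 at 0 and 18, NCED3 at 3787 and 1446 and RD26 at 2603 and 1061 in WT replicates 1 and 2. The log2 fold change without WT replicate 1 was 4.60 for COR27, 3.91 for AT4G33980, 4.79 for GRP9, 3.24 for FKF1, -2.05 for NCED3 and -1.94 for RD26. ATSDI1 was then not called (adjusted p = 0.0667). Without WT replicate 2 the value was 6.73 for COR27, 5.97 for AT2G04050, 4.85 for AT2G18193 and 5.93 for FKF1. AT4G33980, then at 0 counts in WT, was at least 83.1-fold higher with a floor of 3 counts over the remaining WT library. The log2 fold change of ATSDI1 was -4.28 or -2.67 without ClpD-OE replicate 1 or 2.

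Nuclear-encoded photosynthesis genes fell as a group, with a median log2 fold change of -0.75 over 57 tested members (camera adjusted p = 7.00e-56, and adjusted p = 0.503 with an estimated correlation). The count called lower was 54, and 55 adjusted over the list alone. LHCB2.1 (AT2G05100), a light-harvesting protein gene of photosystem II, had 4532 ± 429 CPM in WT and 1913 ± 43.5 in ClpD-OE (SD, n = 2), 2.37-fold lower. LHCA4 of photosystem I was 2.05-fold lower and PSAD2, a photosystem I subunit gene, 2.03-fold lower. LHCB1.3 fell 1.55-fold and RBCS1A, which encodes the Rubisco small subunit, 1.31-fold, and the LHCB1 and RBCS genes have near-identical copies among which the authors' counting could divide reads. The members that did not pass were LHCA5, RBCS1B and FNR2, with log2 fold changes of -0.31, -0.16 and 0.23, and 1 member was called higher without WT replicate 2. RBCS1A was not called with library totals (log2 fold change -0.17, adjusted p = 0.0857) or with the newer quasi-likelihood fit (adjusted p = 0.0809). These 57 genes took 23.4% of all counts in WT replicate 2, slightly more in WT replicate 1, and 16.3% and 16.6% in the ClpD-OE libraries. The WT libraries themselves differed little here, with a median log2 difference of -0.065 between replicate 2 and replicate 1.

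Chlorophyll synthesis genes and chloroplast regulators moved the same way, with 9 of 18 tested members called lower and 0 higher (10 lower adjusted over the list alone). Their median log2 fold change was -0.53 (camera adjusted p = 8.44e-09, and adjusted p = 0.503 with an estimated correlation). The WT libraries differed in this list by a median log2 value of -0.16 (replicate 2 minus replicate 1). GLK1, which encodes a transcription factor that activates photosynthesis genes, was 2.62-fold lower (log2 fold change -1.39, SE 0.146). CAO, which encodes the enzyme that makes chlorophyll b, was 2.55-fold lower, and GUN4, a regulator of chlorophyll synthesis, 2.21-fold lower. Without WT replicate 2, 1 member was called higher.

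**Figure D2:**
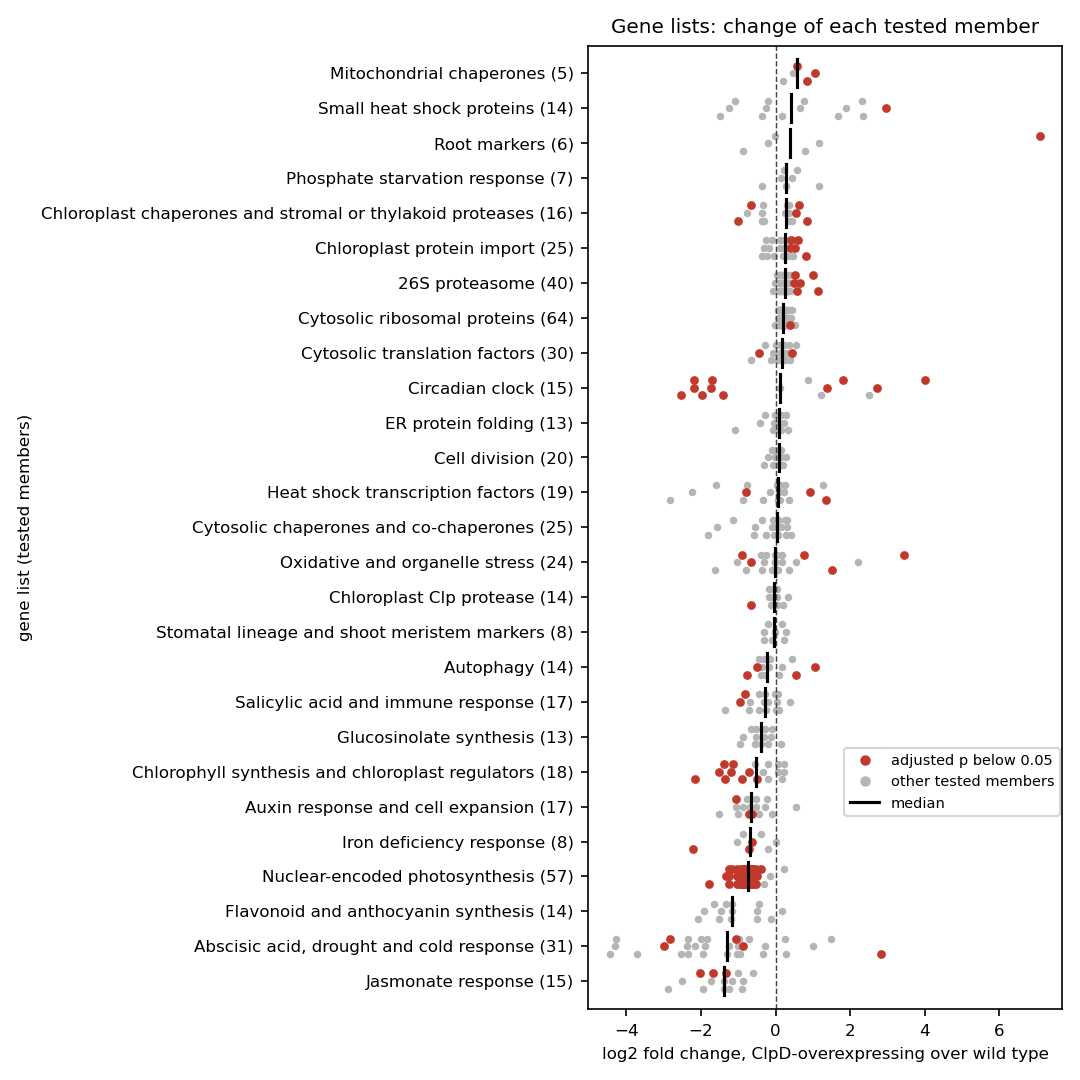
Log2 fold change of ClpD-OE over WT (horizontal axis) for each tested member of 27 gene lists (vertical axis, tested members in brackets), in red where the edgeR adjusted p was under 0.05 and in grey otherwise, with a black bar at the median. The photosynthesis list has 54 of 57 members in red at the left of 0, and the clock list has 4 at the right and 7 at the left; the point near 7 is the fitted value of PRP3, which had 0 counts in WT, and is no measure of its fold.

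Genes of protein import into chloroplasts rose as a group, with 5 of 25 called higher and 0 lower (10 higher and 3 lower adjusted over the list alone). Their median log2 fold change was 0.26 (camera adjusted p = 0.0114, and adjusted p = 0.730 with an estimated correlation). TIC110, a component of the inner envelope translocon, was 1.75-fold higher (log2 fold change 0.80, SE 0.0971), TOC33, an outer envelope receptor gene, 1.51-fold and TIC40 1.45-fold. TOC159, the main receptor gene for photosynthetic precursors, was 1.34-fold higher (adjusted p = 0.0481). CDC48A, whose product extracts outer envelope proteins for degradation, had a log2 fold change of 0.26 and did not pass (adjusted p = 0.0931). Without WT replicate 1, 1 import gene was called higher, and TOC33, TIC40 and TOC159 were not called (adjusted p = 0.0766, 0.0799 and 0.0954), while without WT replicate 2 there were 8 higher and 1 lower. For the 26S proteasome, 6 of 40 members were called higher and 0 lower (17 higher adjusted over the list alone), with a median of 0.26 (camera adjusted p = 2.70e-06, and adjusted p = 0.730 with an estimated correlation). The proteasome genes with the smallest p were RPN8B (2.19-fold higher), RPT5B (1.99-fold) and RPT6B (1.56-fold), each with a close paralog, and without WT replicate 1 the list had 2 members called higher, RPT6B not among them (adjusted p = 0.0728).

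The mitochondrial chaperone list had 3 of 5 members called higher (4 adjusted over the list alone), with a median of 0.57 (camera adjusted p = 5.97e-05, and adjusted p = 0.503 with an estimated correlation). HSP60-2 was 2.08-fold higher (log2 fold change 1.05, SE 0.0899), MTHSC70-1 1.80-fold and MTHSC70-2 1.49-fold, the last not called with DESeq2 size factors (adjusted p = 0.0524) or without either WT library. Among 24 oxidative and organelle stress genes, 3 were called higher and 2 lower, and the list was not called (adjusted p = 0.445), with 1 lower without WT replicate 1 and 5 lower without WT replicate 2. UPOX (AT2G21640) went from 1.91 ± 0.307 CPM to 21.1 ± 2.49 (SD, n = 2), and NAC013, a transcription factor gene of mitochondrial retrograde signalling, was 2.83-fold higher. Chloroplast chaperones and proteases went both ways, with 3 of 16 called higher and 2 lower (8 and 7 adjusted over the list alone) and no call for the list (adjusted p = 0.859). HSP90C, the plastid HSP90 gene, was 1.78-fold higher and FTSH1, a thylakoid protease gene, 1.58-fold lower. The median log2 fold change of this list was 0.27, and 0.25 without WT replicate 1, a value that rests on 1 WT library. Fewer members were then called higher, and as many lower. Without WT replicate 2, more were called in both directions.

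Cytosolic ribosomal protein genes had a median log2 fold change of 0.20 over 64 members (camera adjusted p = 1.05e-04, and adjusted p = 0.806 with an estimated correlation), although RPL8C (1.31-fold) was the only member called, and 0 were called adjusted over the list alone or without WT replicate 1. Cytosolic translation factors were not called as a list (adjusted p = 0.0582), but were called higher with library totals (adjusted p = 0.00384), without a filter (adjusted p = 0.0106) and without ClpD-OE replicate 2 (adjusted p = 0.0283), with EIF2A2 1.36-fold higher and EIF5A3 1.35-fold lower, neither called without WT replicate 1. EIF5A3 was not called without WT replicate 2 either (adjusted p = 0.0640). Among 14 autophagy genes 2 were called higher and 2 lower (list adjusted p = 0.502), with log2 fold changes of 1.07 for ATG8D and -0.50 for ATG8F, and 0 of the 14 were called without WT replicate 1. Of 13 ER protein folding genes (list adjusted p = 0.837) and 20 cell division genes (list adjusted p = 0.763), 0 were called by edgeR or DESeq2, with 3 and 0 at an unadjusted p under 0.05, and 1 ER gene was called lower without WT replicate 2.

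Of 19 tested heat shock transcription factor genes, 2 were called higher and 1 lower, and the list was not called (adjusted p = 0.883, with a median of 0.055 and a mean of -0.25). HSFA8 was 2.53-fold higher (log2 fold change 1.34, SE 0.174), HSFA3 1.90-fold higher and HSFB2A 1.72-fold lower. Among 14 small heat shock protein genes 1 was called by edgeR, HSP17.6C-CI, at 7.76-fold higher, while 4 were called higher by DESeq2 and 6 were higher at an unadjusted p under 0.05. The list, with a median of 0.41, was not called (camera adjusted p = 0.120, and adjusted p = 0.814 with an estimated correlation). With the replicate number as a block, a pairing that the labels do not state, this list was called higher by camera. The cytosolic chaperone and co-chaperone list had a median of 0.024 and a mean of -0.17 (adjusted p = 0.859). Replicate 1 exceeded replicate 2 in both groups in HSFA2, HSP101, HSP70-4 and HSP90.1. The median log2 difference of replicate 2 from replicate 1 was -0.63 in WT and -0.21 in ClpD-OE for the cytosolic chaperones, and -0.43 and -0.65 for the small heat shock proteins. HSFA2, the heat-induced factor gene, had 870 and 52 counts in WT replicates 1 and 2 and 182 and 71 in ClpD-OE (log2 fold change -2.25, SE 1.24, adjusted p = 0.300). HSP101, the cytosolic disaggregase gene, had 1038 and 205 counts in WT and 321 and 218 in ClpD-OE (adjusted p = 0.250). HSP70-4 had 3121 and 729 counts in WT and 2875 and 1343 in ClpD-OE, and HSP90.1 had 879 and 280 in WT and 991 and 528 in ClpD-OE, with log2 fold changes of -0.25 and 0.022 (adjusted p = 0.861 and 0.986). Without WT replicate 1, 1 heat shock factor gene was called higher and 0 lower, and HSP17.6C-CI was not called (adjusted p = 0.0826). The cytosolic chaperone list was then called higher, with a median of 0.30 (adjusted p = 2.10e-04), and the small heat shock protein list too, with a median of 0.31 (adjusted p = 0.00387). Without WT replicate 2, the cytosolic chaperone list was called lower instead, with a median of -0.29 (adjusted p = 0.00634), and HSFA2 and HSP101 were called lower, at -3.18 and -2.35, among 6 heat shock factor, 4 cytosolic chaperone and 3 small heat shock protein genes called lower. The single genes turned with the WT library as well. With WT replicate 1 left out, the edgeR log2 fold changes were 1.01 for HSFA2, 0.12 for HSP101, 1.26 for HSP70-4 and 1.17 for HSP90.1, values that rest on 1 WT library. With WT replicate 2 left out, HSP70-4 and HSP90.1 were at -0.97 and -0.61 (adjusted p = 0.209 and 0.324). HSFA2, HSP70-4 and HSP90.1 were at -3.08, -0.89 and -0.49 without ClpD-OE replicate 1. Without ClpD-OE replicate 2 they were at -1.74, 0.20 and 0.40, so the signs of HSP70-4 and HSP90.1 also turned with the ClpD-OE library. Without ClpD-OE replicate 2 the small heat shock protein list was called higher, with a median of 0.16 (adjusted p = 0.00156).

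Abscisic acid, drought and cold response genes fell as a list, with a median of -1.30 over 31 members (camera adjusted p = 1.63e-06, and adjusted p = 0.730 with an estimated correlation), of which 4 were called lower and 1 higher (17 and 3 adjusted over the list alone). NCED3 and RD26, named above, were called lower, CBF1 and CBF2, transcription factor genes of cold acclimation, were 1.85-fold and 2.07-fold lower, and DREB2C was 7.14-fold higher. The WT libraries differed in this list by a median log2 value of -1.41 (replicate 2 minus replicate 1), and without WT replicate 1 its median was -0.65 with 7 members called lower and 0 higher, CBF1, CBF2 and DREB2C not among them (adjusted p = 0.0541, 0.0822 and 0.0701), and without WT replicate 2, 23 were called lower. Jasmonate response genes had a median of -1.37 over 15 members, 3 called lower and 0 higher, and 9 lower adjusted over the list alone (camera adjusted p = 7.74e-08, and adjusted p = 0.730 with an estimated correlation). LOX2 and AOC1, genes of jasmonate synthesis, were 3.22-fold and 4.07-fold lower and the transcription factor gene MYC2 had a log2 fold change of -1.32. The median log2 difference of replicate 2 from replicate 1 in this list was -0.85 in WT and -1.01 in ClpD-OE. The jasmonate median was -0.82 without WT replicate 1, with 1 member called lower, and AOC1 and MYC2 were at -1.39 and -0.89 and not called (adjusted p = 0.0844 and 0.0540). AOC1 was not called with DESeq2 size factors either (adjusted p = 0.0512), and 10 were called lower without WT replicate 2. Auxin response genes had a median of -0.66 over 17 members, 3 called lower and 0 higher, and 5 and 1 adjusted over the list alone (camera adjusted p = 8.41e-04, and adjusted p = 0.730 with an estimated correlation), with GH3.5 2.09-fold, GH3.3 1.63-fold and IAA19 1.55-fold lower. The auxin median was -0.38 without WT replicate 1, with 1 called lower, IAA19 and GH3.3 not passing (adjusted p = 0.115 and 0.110). GH3.3 was not called without WT replicate 2 either (adjusted p = 0.0755). Salicylic acid and immune response genes had a median of -0.29 over 17 members, 2 called lower, ICS1 (1.94-fold) and WRKY46 (1.77-fold), and 4 adjusted over the list alone, with a camera adjusted p = 0.0150 and an adjusted p = 0.730 with an estimated correlation. Of its members 0 were called without WT replicate 1 and 1 without WT replicate 2. WRKY46 was not called in either case (adjusted p = 0.125 and 0.0593). That list was not called without WT replicate 2 (adjusted p = 0.110) or without ClpD-OE replicate 2 (median -0.062, adjusted p = 0.190), and its median was -0.52 without ClpD-OE replicate 1.

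Flavonoid and anthocyanin synthesis genes had a median of -1.18 over 14 members with 0 called by edgeR, also adjusted over the list alone, 4 called lower by DESeq2 and 9 lower at an unadjusted p under 0.05 (camera adjusted p = 0.00166, and adjusted p = 0.730 with an estimated correlation). The WT libraries differed in them by a median of -1.28, and the median without WT replicate 1 was -0.44. Without WT replicate 2, edgeR called 10 of the 14 lower. Glucosinolate synthesis genes had a median of -0.40 over 13 members, also with 0 called by edgeR, 2 called lower by DESeq2 and 6 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0155, and adjusted p = 0.730 with an estimated correlation). The glucosinolate list was not called without WT replicate 1 (median -0.23, adjusted p = 0.111), while 7 members were called lower without WT replicate 2. Iron deficiency genes had a median of -0.68 over 8 tested members, with 3 called lower, 4 adjusted over the list alone, and 0 without WT replicate 1 (camera adjusted p = 0.00227, and adjusted p = 0.503 with an estimated correlation). IMA3, which encodes a peptide that promotes iron uptake, was 4.62-fold lower, NAS4 1.64-fold and OPT3 1.57-fold lower. NAS4 was not called by DESeq2 (adjusted p = 0.0661) or without WT replicate 2 (adjusted p = 0.0757). Phosphate starvation genes were not called as a list (adjusted p = 0.206). The sugar starvation list had 4 tested members, too few for the list test, with 0 called by edgeR, 1 lower by DESeq2, and 2 lower and 1 higher at an unadjusted p under 0.05, and 1 was called higher with either WT library left out.

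Circadian clock genes changed in both directions, with 4 of 15 called higher and 7 lower (7 and 7 adjusted over the list alone) and no call for the list (adjusted p = 0.759). Higher were TOC1 (2.62-fold), LUX (3.47-fold) and ELF4 (6.54-fold), which are expressed toward the evening, and FKF1. Lower were the morning genes CCA1 (4.52-fold), LHY (4.55-fold), PRR9 (5.85-fold) and RVE8 (3.95-fold), with COL1, COL2 and CDF1. In all 15 genes WT replicate 2 differed from WT replicate 1 in the direction in which ClpD-OE differed from WT. Both comparisons use the WT libraries, and ClpD-OE libraries were simulated with no change against them, 100 times each, with genes drawn independently. How many unchanged genes go that way depends on where the simulated libraries are placed, so no single value stands for no change. On average 7.35 of 15 genes went that way at the WT mean, midway between the WT libraries (range 2 to 12). At the level of WT replicate 1 the average was 0.28 (range 0 to 2), and at the level of WT replicate 2 it was 14.7 (range 13 to 15). CCA1, for example, had 1170 and 630 counts in WT and 308 and 201 in ClpD-OE. Without WT replicate 1, 3 clock genes were called higher and 4 lower, and without WT replicate 2, 7 and 7.

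Markers of other tissues gave few calls. Of 13 root markers 6 were tested and 1 was called (list adjusted p = 0.246), PRP3, a root hair gene with 0 counts in WT and 19 in each ClpD-OE library. It was at least 10.1-fold higher with a floor of 3 counts over the WT group, and was not called without WT replicate 1 or 2 (adjusted p = 0.0925 and 0.0505). PYK10, an abundant beta-glucosidase gene of root and hypocotyl, had a log2 fold change of -0.012 (SE 0.0816, adjusted p = 0.945). Of 8 tested stomatal lineage and shoot meristem genes, 0 were called by edgeR or DESeq2 and 1 had an unadjusted p under 0.05 (list adjusted p = 0.913), and none of 13 seed storage and embryo genes had enough counts to be tested.

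At an adjusted p under 0.05, 13 of 27 lists were called by camera with a preset correlation, 4 higher and 9 lower, and 0 of the 13 calls held with an estimated correlation or by fry (1 and 8 of all 27 lists at an unadjusted p under 0.05). When each library was left out in turn, edgeR called 524 genes without WT replicate 1, 2781 without WT replicate 2 and 0 without either ClpD-OE replicate, where 3603 and 3034 genes had an unadjusted p under 0.05 and DESeq2 called 551 and 341. With library totals in place of TMM scaling the median log2 fold change of all genes was 0.23, beside 0.0011 with TMM. Library totals gave 2699 genes called higher and 577 lower, beside 812 and 740 with TMM. Of the genes named above, ATG8F, EIF5A3, WRKY46, IAA19, GH3.3, NAS4 and RBCS1A were then not called (adjusted p of 0.0534 to 0.155), and CDC48A was called higher (adjusted p = 0.0226). Without a filter, MTHSC70-2, RPL8C, EIF5A3, GH3.3, NAS4 and TOC159 did not pass (adjusted p of 0.0503 to 0.0549). In the authors' deposited table the genes with a false discovery rate under 0.05 numbered 2054, 927 higher and 1127 lower, and 1446 of them were among the 1552 called here, all in the same direction. Both sets of calls draw on the same libraries, so this overlap is no independent evidence.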

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

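DESeq2 with a library left out and the newer quasi-likelihood fit were chosen after the data were seen; the other alternatives were planned. The count of 1552 genes stayed within 1.5 times, at 1406 to 2154, with DESeq2 size factors, either other filter, DESeq2 and the newer quasi-likelihood fit. The legacy fit and the removal of organelle-encoded genes changed nothing by construction, since the installed default is the legacy fit and the table lists 0 such genes. Library totals called 3276 genes, and a change of at least 2-fold left 638 and an adjusted p under 0.01 left 1. Without a library, edgeR called between 0 and 2781 genes. DESeq2 called 537 without WT replicate 1, 1675 without WT replicate 2, 551 without ClpD-OE replicate 1 and 341 without ClpD-OE replicate 2; the cause was not tested beyond the smaller number of samples, where the lone library is assumed to vary like the other group. The smaller number of samples cannot by itself account for the rise in edgeR calls without WT replicate 2. There the ClpD-OE pair alone set the spread, with an SD of the log2 difference of 0.36, beside 0.44 between the WT libraries. All 1552 genes kept their direction without WT replicate 1, which is a weak check, since these genes were selected with the same libraries.

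The replicate numbers are shared between groups, but the labels do not say that they mark a pair. With the replicate block 3513 genes were called, 1628 higher and 1885 lower, and the deviations of same-numbered libraries correlated at 0.265 across genes, which with 2 pairs does not establish pairing. Of the lists, the small heat shock proteins gained a call with the block (higher, adjusted p = 0.0295), and the other 26 kept their side of the threshold.

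The log2 fold change of CLPD lay between 3.48 and 3.65 without a library, and its edgeR adjusted p was 0.0674 without ClpD-OE replicate 1 and 0.0842 without ClpD-OE replicate 2. Of 13 called lists, 0 were called with an estimated correlation and 0 by fry, and of all 27 lists 1 and 8 had an unadjusted p under 0.05 there. Cytosolic translation factors, not called otherwise, were called higher with library totals (adjusted p = 0.00384), without a filter (0.0106) and without ClpD-OE replicate 2 (0.0283). The cytosolic chaperone list, not called with all libraries, was called higher without WT replicate 1 (median 0.30) and lower without WT replicate 2 (median -0.29). Of the 61 called named genes besides CLPD, 28 lost their call without WT replicate 1, 6 without WT replicate 2 and 61 without either ClpD-OE replicate, 7 under library totals (RBCS1A among them, at -0.17) and 2 with DESeq2. HSFA2 and HSP101 were called lower without WT replicate 2, at -3.18 and -2.35, and were at 1.01 and 0.12, not called, without WT replicate 1. In the simulated counts, 12.9% of genes changed 1.5-fold were recovered. The simulated test made 126 calls, beside 1552 in the real comparison, and the p needed to pass the adjustment depends on how many genes change. The simulated recovery therefore cannot tell what share of 1.5-fold changes was missed in these data.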

Other observations

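The tests in this part, other than the planned refits with library totals or with a library left out, were chosen after the results were seen. Genes were also grouped by the annotation in the deposited table, into 236 families of at least 8 tested genes, and 22 families were called by camera with the preset correlation, 16 higher and 6 lower. None of these 22 calls held with an estimated correlation, where the smallest adjusted p was 0.920 and 2 families had an unadjusted p under 0.05. The pentatricopeptide repeat superfamily, RNA-binding proteins of chloroplasts and mitochondria, had 43 of 181 members called higher and 1 lower, a median log2 fold change of 0.74 and positive values in 169 members (adjusted p = 1.05e-21, and adjusted p = 0.920 with an estimated correlation). Without WT replicate 1, 5 members were called higher and the median was 0.65. DEAD/DEAH-box RNA helicases had 7 of 20 members higher and a median of 0.56 (adjusted p = 1.47e-08, and adjusted p = 0.920 with an estimated correlation), and 3 members were called higher without WT replicate 1. ACC2, the gene of the chloroplast-targeted homomeric acetyl-CoA carboxylase, had a log2 fold change of 2.46 (SE 0.141), and LON1, a gene of an organelle protease, of 1.25 (SE 0.0932), with an edgeR adjusted p of 0.0188 for both. Both genes were picked after the results were seen.

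Because LSU1 and ATSDI1 were among the largest falls, 10 genes that respond to sulfur limitation were looked at together, a list drawn up with some of their values already known and so no independent evidence. Of the 10, 9 were called lower, with a median log2 fold change of -1.86 (camera p = 3.29e-24, and p = 0.0581 with an estimated correlation). LSU3 was at -2.48 (SE 0.187), GGCT2;1 at -2.05 (SE 0.385), SHM7 at -1.60 (SE 0.167) and APR3 at -1.48 (SE 0.156), and BGLU28 did not pass (edgeR adjusted p = 0.0698). The WT libraries differed in these genes by a median of -0.25, and without WT replicate 1 the median was -1.68 with 5 called lower. APR3 carries the name 45385 in the deposited table, 1 of 22 gene names there that consist of digits only.

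Clock genes differed between the groups, and in 15 of 15 tested clock genes WT replicate 2 differed from replicate 1 toward ClpD-OE, as it did in 80.7% of the 1552 called genes. Simulated against the real WT libraries, with genes drawn independently, unchanged ClpD-OE libraries at the WT mean gave 7.35 of 15 (range 2 to 12) and 49.5% (range 46.1% to 52.8%). Libraries at the level of WT replicate 1 gave 0.28 of 15 (range 0 to 2) and 25.6% (range 22.4% to 28.8%). Those at the level of WT replicate 2 gave 14.7 of 15 (range 13 to 15) and 73.7% (range 71.3% to 76.0%). These values depend on where the unchanged libraries were placed. With WT replicate 1 out of place, the shared controls alone could give the clock gene agreement and part of that in the called genes. This shift prompted the idea that libraries were collected at other times of day or under other conditions, and so is no test of it. Such a difference and an effect of overexpression cannot be told apart, since 7 clock genes were called against WT replicate 2 alone and the time of collection is not given in the sources used here.

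For the lower photosynthesis genes, the difference between the WT libraries is argued against by a median log2 shift of -0.065 between them (SD over members 0.126), beside -0.75 between the groups. Scaling is argued against as the whole cause, since with library totals the median was -0.53 and 52 members were still called lower. Stomatal lineage genes, which are active in cotyledons and leaves, had a median of -0.048 over 6 genes (SD over members 0.235). These genes need not follow the amount of green tissue, so a smaller share of cotyledons and leaves cannot be excluded by them. A lower share of mesophyll within those organs was not tested. Nor was a difference in time or conditions of collection, left open above for the clock genes. A change in the expression of these genes in the overexpressing line may account for the pattern, as a hypothesis.

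Besides PRP3, the root hair genes COBL9, EXPA7, EXPA18, RHD6 and LRX1 summed to 2 and 1 counts in the WT libraries and 13 and 28 in the ClpD-OE libraries, a ratio of 10.8 (exact 95% interval 3.46 to 54.7, counting error only) that was 17.0 without WT replicate 1 and 6.84 without ClpD-OE replicate 2. Of 18 extensin family genes 8 were tested and 4 called higher by edgeR, 3 of these with 0 counts in WT, and 0 were called without WT replicate 1 or either ClpD-OE replicate. More root tissue in ClpD-OE may be the source and cannot be excluded: the 5 tested root markers other than PRP3 had a median of -0.012 but ran from -0.88 (NRT2.1) to 1.17 (CASP1), and the high level of PYK10 would hide a small share, while ADF8, also active in root hairs, was at -0.20. Reads moved between near-identical extensin copies cannot be judged either, since the family sum gave a ratio of 1.08 but 3 abundant genes held 99.8% of its WT counts and fix that sum. An effect of overexpression on root hairs stays open and untested.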
